A study of Drosophila melanogaster with 3 samples.

How the data were processed

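ChIP-seq was done on whole embryos of 1 transgenic line, in 3 biological replicates that form 1 group. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated with an antibody to GFP. The antibody field of the labels names CG6854, while the description names an antibody to GFP. Replicate numbers were taken from the labels. The labels speak of biological replicates, and nothing further was given on how the embryo collections were separated.

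The deposited files were peak lists in narrowPeak format on dm3 and dm6, per the submitters' file list. The authors derived each replicate's relaxed list from that replicate's alignments and 1 control file, the pooled list from the alignments of the 3 replicates, and the optimal list from the replicate and pooled lists by IDR, per the submitters' file list. The aligner, peak caller and IDR threshold were not given in the sources used here. The signal column of the deposited lists is the peak's own value as the authors' caller gave it, and it was used to rank and filter peaks within a list. The column of −log10 q-values in the deposited lists was not used in any test. Every relaxed list held 30000 peaks. A fixed length means that weak entries are background as well as binding. Alignments, control libraries and coverage were not analysed here, so depth is unknown and an excess over the control could not be recomputed.

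Coordinates are those of the files on dm6, written from 1. The annotation was Ensembl release 115 of the same assembly, Release 6, and sequence came from the same assembly. Annotated transposable elements were left out. For 1 optimal peak, the caller's summit lay past the end of the trimmed peak and was set to its last base. A summit within 500 bp of an annotated TSS counted as promoter, and others were classed in the order 5' untranslated region, coding exon, 3' untranslated region, other exon, intron and intergenic. Optimal peaks were compared with the remaining 26455 pooled peaks, which could have passed the IDR threshold, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family and a threshold of 0.05 on the adjusted p. Odds ratios had 0.5 added to each cell. Shares carry Wilson 95% intervals, which cover counting error only.

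There were 26 gene lists, given by symbol, name pattern or gene type. The list called larval cuticle was set by gene name (Lcp, Ccp, Cpr, TwdlA and TwdlB) and not by stage. List members with a pooled summit within 500 bp of a TSS were compared with the other protein-coding genes that had one, also for the transfer, small nuclear and small nucleolar RNA genes. Symbols nos, Z4 and Dl had no unique match and were left out, as was CG6854, an older name shared by both genes of the tagged locus. Replicate overlap was set against 1000 circular shifts, the signal of promoter peaks against 100000 permutations, and gene length against 10000 random lists in 10 bins. For the RNA gene lists the random lists held protein-coding genes of the same length bin, so the match is only as close as the bin. Motifs (24 consensus sequences) and all 6-mers were searched on both strands within 100 bp of the summit. The matched background drew 3545 remaining windows in 20 GC bins and by promoter class.

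Genes were named by a fixed rule: the nearest protein-coding gene of each of the 20 optimal peaks with the highest signal, the genes of the tagged locus, up to 4 members per list with the strongest optimal promoter peak and up to 2 members, first by alphabet, without one, and the gene nearest to any peak in the top 10 of every replicate. Groups, tests, lists, motifs, the rule and most alternatives were fixed before the data were examined. The alternatives were other promoter windows, backgrounds, overlap rules and list lengths, the stronger part of the optimal list, the optimal peaks held by the top lists of both other replicates for each replicate in turn, and the dm3 lists. That setting filters the optimal list of all 3 replicates, and the pooled signal and the remaining peaks still contain the replicate not asked for, so it is no analysis without that replicate's data. Merging overlapping peaks and the test of the side of the TSS were chosen after seeing the data.

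The tests were tested on simulated data. For the annotation comparison, with 30000 simulated summits, a promoter log2 odds ratio of 1.22 was recovered as 1.22. For the gene list comparison, with 7000 genes, a list with a raised share was recovered in 95.5% of simulations. In 12% of them at least 1 of the unchanged lists passed. The simulated lists were longer than most of those tested, such as the Hox list with 4 genes, so the 95.5% does not apply to short lists. For the motif comparison, with 30000 windows, a planted log2 odds ratio of 1.08 was recovered as 1.07. For the replicate overlap, with 2000 peaks per list, a shared part of 50% was recovered as 50.5%. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9, with random seed 1.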

Results

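Chromatin from whole fly embryos (*Drosophila melanogaster*, mixed sex, 0 to 24 hours after egg laying) was immunoprecipitated with an antibody against green fluorescent protein (GFP) and sequenced (ChIP-seq). The embryos came from a transgenic line in which GFP was fused to the carboxyl end of a fly protein. The labels name that protein in different ways, as the product of CG45071, of CG6854 and of CTPsyn, the gene for CTP synthase (Ctps in the annotation), the enzyme that makes the nucleotide CTP from UTP. There was 1 group with 3 biological replicates, so the comparisons are between replicates and between classes of peaks. Each replicate had a relaxed list of 30000 peaks, which holds background as well as binding, and the pooled replicates had another list of 30000. The optimal list held 3545 peaks on the dm6 build that came from an analysis of irreproducible discovery rate (IDR, which asks how far down ranked lists the replicates stay alike). Peaks in the optimal list had a median width of 436 bp. Read numbers per library are not known from peak lists, so the sequencing depth behind each peak is unknown.

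The strongest peaks were the same regions in all 3 replicates, and they lay mostly beside promoters. Of the 20 optimal peaks with the highest signal, the peak nearest to CG11050 ranked first and lay in an intron (2L:6612383-6612965, dm6, 1028 bp from the nearest protein-coding transcription start site, TSS). It ranked 2, 1 and 1 in replicates 1, 2 and 3. The peak at the promoter of Ugalt, which encodes a UDP-galactose transporter (X:2703700-2704069), ranked 1, 2 and 2, with its summit 29 bp from the TSS. The peak nearest to cbt (cabut, a zinc-finger transcription factor) lay in an intron at 2L:480887-481284 and ranked 3 in every replicate. CG4004 (X:12750839-12751607, in an exon outside the coding and untranslated classes), Gapdh2, a glycolytic enzyme gene (promoter, X:15867787-15868169), Trl, which encodes GAGA factor (intron, 3L:14759324-14759726), and CG14100 (promoter, 3L:19590448-19590774) were also within the top 10 of every replicate.

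Further down the same 20, promoter peaks belonged to px (2R:22514105-22514482), CenG1A (2L:13835310-13835632), CG18549 (3R:12449002-12449332), CG11309 (3L:21304407-21304732), PNPase (3R:31404490-31404822), Chro, which encodes the chromatin protein Chromator (3L:22878739-22879076), CG13390 (2L:8376727-8377058), CG1635 (3R:31588371-31588712), mRpL41 (2R:15217579-15217895) and Tina-1 (2R:24942390-24942760). The peaks nearest to CG32772 (X:4910180-4910551), Tlk, a protein kinase gene (X:3742045-3742379), and Lk6, another kinase gene (3R:11760889-11761266), lay in introns. Peak signal was the authors' own value for each peak, and it fell from 2397 at CG11050 to 1108 at Lk6.

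Agreement between replicates was measured on equal lists, the 3545 highest-ranked peaks of each. Replicates 1 and 2 shared 64.4% of these peaks, replicates 1 and 3 shared 63.7%, and replicates 2 and 3 shared 68.5%. The mean over the 3 pairs was 65.5% ± 2.63 (SD). Lists shifted at random along the chromosomes shared 1.03%, 1.05% and 1.03% on average, and none of the 1000 shifts per pair reached the observed share (one-sided permutation p = 0.001 for each pair, the smallest the shifts can give). Such shifts move peaks off promoters, which held 52.8% of optimal summits and 13.6% of the same summits after shifting. The chance value therefore does not account for a preference for promoters that the lists share.

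Of the 3545 optimal peaks, replicate 1 held 74.0% among its own top 3545 (Wilson 95% interval 72.6 to 75.4), replicate 2 held 82.1% (80.8 to 83.3) and replicate 3 held 80.7% (79.4 to 82.0). All 3 replicates held 1926 of them, 54.3% (52.7 to 56.0), and 42 were in none of the 3 top lists. With the whole relaxed lists, 96.6% of the optimal peaks were found in all 3 replicates. The optimal peaks were exactly the 3545 highest-signal peaks of the pooled list.

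Optimal peaks lay at promoters more often, and in coding sequence far less often, than the weaker regions of the same pooled list. A promoter, defined as 500 bp on either side of an annotated TSS, held 1872 of 3545 optimal summits, 52.8% (Wilson 95% interval 51.2 to 54.4), against 8073 of 26455 remaining summits, 30.5% (30.0 to 31.1). Coding exons held 8 optimal summits, 0.226% (0.114 to 0.445), against 5.76% of the remaining ones. Introns held 34.4% against 42.6%, intergenic sequence 10.1% against 16.6%, 3' untranslated regions 0.987% against 2.42%, and 5' untranslated regions 0.592% against 1.08%. Other exons were close, at 0.874% against 0.926%.

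The promoter log2 odds ratio was 1.35 (two-sided Fisher's exact test, adjusted p = 3.92e-145 over 7 classes), and that of coding exons was -4.67 (Fisher's exact test, adjusted p = 1.06e-71). Fisher's exact test gave an adjusted p of 6.12e-21 for introns, 2.89e-25 for intergenic sequence, 5.17e-09 for 3' untranslated regions, 0.00518 for 5' untranslated regions and 0.851 for other exons. The classes share 1 total, so a higher promoter share lowers the rest. Outside promoters, introns held 1219 of 1673 optimal and 11282 of 18382 remaining summits. Introns and other exons thus had the higher share among optimal peaks there, and the other classes kept the lower one. That comparison was not tested. With a promoter window of 100 bp the intergenic log2 odds ratio changed sign to 0.15 and passed as higher, the intron value shrank to -0.059 with no call, and the promoter value was 0.93. The call for 5' untranslated regions (log2 odds ratio -0.85) ended with that window (0.031), among optimal peaks held by the top lists of both replicates 1 and 3 (-0.73) and against circular shifts (-0.40). Peaks close together are not independent, so these p-values describe the lists and not replicate embryos.

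**Figure D1:**
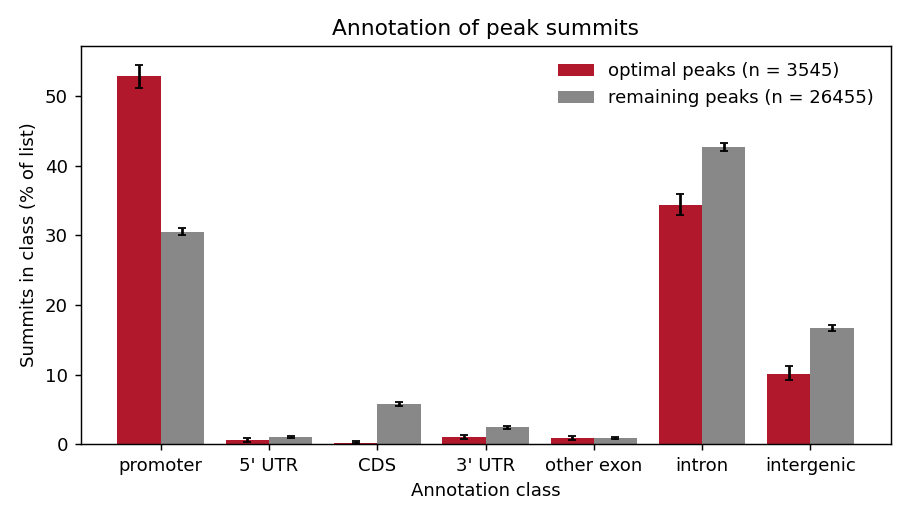
Share of peak summits (% of list, y axis) in each annotation class (x axis) for the 3545 optimal peaks and the 26455 remaining pooled peaks; bars are shares and error bars are Wilson 95% intervals. Promoters hold 52.8% of optimal and 30.5% of remaining summits, and coding exons (CDS) hold 0.226% and 5.76%.

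Optimal summits near a TSS sat on its upstream side. Within 500 bp of the nearest protein-coding TSS there were 1757 optimal summits, of which 1230 were upstream, 70.01% (Wilson 95% interval 67.8 to 72.1), against 50.7% of 7322 remaining summits (49.5 to 51.8). The median position was -94 bp for optimal and -3 bp for remaining summits. The log2 odds ratio was 1.18 (two-sided Fisher's exact test, p = 1.49e-49), in a test that was added after the data had been seen. With a window of 100 bp the log2 odds ratio was 0.36 and the upstream shares were 56.9% and 50.6%.

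**Figure D2:**
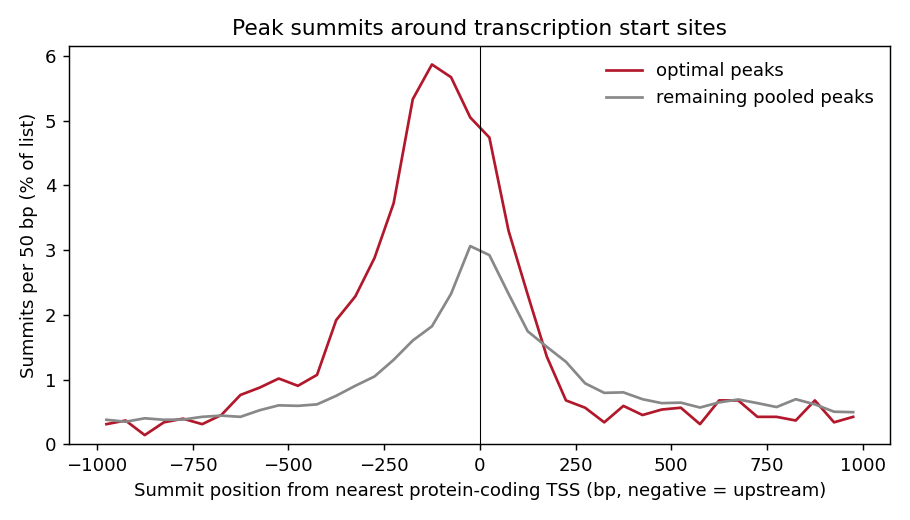
Position of peak summits from the nearest protein-coding TSS (x axis, bp, negative values upstream) as the share of all summits of the list per 50 bp (y axis, %), for optimal and remaining pooled peaks. The median of the summits within 500 bp is -94 bp for the optimal and -3 bp for the remaining peaks.

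Promoter peaks were stronger than other optimal peaks by a small margin. Their median signal was 174 (n = 1872 peaks) against 163 (n = 1673), a difference in mean log10 signal of 0.0393 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Promoters held 72.0% of the peaks ranked 1 to 100 (Wilson 95% interval 62.5 to 79.9), 63.0% of the next 400 (58.2 to 67.6), 52.0% of the 500 after those (47.6 to 56.3) and 49.7% of the last 1545 (47.2 to 52.2). The difference turned around with a 100 bp window, where the 713 promoter peaks had a median signal of 160 against 169 for the others (difference in mean log10 signal -0.0265).

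No chromosome arm was found to hold more or fewer optimal peaks than remaining peaks. The X chromosome held 610 optimal peaks, 17.2%, against 17.2% of the remaining peaks, with a log2 odds ratio of -0.0029. Arms 2L, 2R, 3L and 3R held 653, 684, 760 and 826 peaks, with log2 odds ratios of 0.034, 0.012, 0.033 and -0.069. The small chromosome 4 held 12 peaks, 0.339% against 0.272% (log2 odds ratio 0.36). No arm passed (two-sided Fisher's exact test, adjusted p = 1 for every arm tested, and the lowest unadjusted p was 0.259, on 3R), and the dm6 lists held no peak on Y or on other contigs. Against arm length, chromosome 4 had fewer optimal peaks than its share of the sequence, 0.339% against 1.01% (log2 ratio -1.57, two-sided exact binomial test, adjusted p = 4.2e-05, with 1 for the same arm in the main test).

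Genes for cytoplasmic ribosomal proteins stood out among the gene lists. Of 85 such genes with any pooled summit within 500 bp of a TSS, 66 had an optimal summit there, 77.6% (Wilson 95% interval 67.7 to 85.2), against 26.9% of 7070 other protein-coding genes (log2 odds ratio 3.21, 95% interval 2.48 to 3.94; two-sided Fisher's exact test, adjusted p = 1.4e-20 over 25 lists). The strongest were at RpS27 (3R:25247365-25247669, rank 95), RpL13A (3R:5624334-5624556, rank 183), RpL30 (2L:19009109-19009368, rank 184) and RpL24 (2L:13395009-13395281, rank 187). The RpS27 peak ranked 58, 134 and 102 in replicates 1, 2 and 3, and the RpL24 peak ranked 281, 167 and 172. RpL10 and RpL10Aa had no optimal peak at a TSS. Among all genes, 1968 of 13986 protein-coding genes (14.1%) had an optimal promoter peak, and 7155 had a pooled one.

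Other genes of protein synthesis and turnover did not pass the main test. Of the translation initiation and elongation factor genes, 15 of 33 had a promoter peak, 45.5% (29.8 to 62.0; Fisher's exact test, adjusted p = 0.27), among them eIF4EHP (3R:24108996-24109390, rank 51), eEF1gamma (3R:29220005-29220289, rank 162), eIF6 (rank 195) and eIF1 (rank 796), while eEF1alpha2 and eEF1beta had none. They passed as higher against all annotated genes (15 of 51, log2 odds ratio 1.38, against 1.15 in the main test). Mitochondrial ribosomal protein genes had 9 of 54, 16.7% (Fisher's exact test, adjusted p = 0.285). Promoter peaks lay at mRpS23 (2L:13835310-13835632, rank 9, the peak also assigned to CenG1A), mRpL41 (rank 18), mRpS10 (3R:15229389-15229691, rank 22) and mRpL23 (rank 154), and mRpL1 and mRpL10 had none. Proteasome subunit genes had 2 of 22, Rpn3 (rank 2379) and Rpn13 (rank 3039), with none at Prosalpha1 and Prosalpha1R (Fisher's exact test, adjusted p = 0.27). In replicate 2 these peaks ranked only 5511 and 18800.

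No list of developmental regulators passed the test against other protein-coding genes with a pooled summit, of which about 27.5% had a promoter peak. Peaks lay at 4 of 13 neural regulator genes, led by the RNA-binding protein gene elav (X:523328-523660, rank 46) and numb (2L:9449425-9449753, rank 215), then brat and da, with none at D and SoxN (Fisher's exact test, adjusted p = 0.929). Segmentation genes had 2 of 14, the gap gene hb (3R:8694203-8694387, rank 797) and the pair-rule gene hairy (hry, rank 1822), and Kr and bcd had none (Fisher's exact test, adjusted p = 0.756). Dorsoventral genes had 4 of 14, namely Meltrin, ush, rho and pyr, without Doc1 and Doc2 (Fisher's exact test, adjusted p = 1). The rho and pyr peaks ranked only 8063 and 16921 in replicate 1. Hox genes had 0 of 4, which allows a share of up to 49.0% (Wilson), and Abd-B and Antp had no optimal promoter peak (Fisher's exact test, adjusted p = 0.929). Mesoderm and muscle genes had 4 of 12, tin (3R:21378505-21378940, rank 682), sls, Tm1 and Mef2, with none at Act57B and Mhc (Fisher's exact test, adjusted p = 0.929). The Enhancer of split list had 2 of 6, E(spl)m3-HLH (rank 432) and E(spl)m7-HLH, and none at E(spl)m2-BFM and E(spl)m4-BFM (Fisher's exact test, adjusted p = 0.929).

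Signalling, hormone, cell cycle and nucleotide synthesis genes did not pass either. Wnt, Notch, Hedgehog and EGFR pathway genes had 8 of 20, with spi, an EGFR ligand gene (2L:19575643-19575864, rank 321), aos, nkd and mam the strongest, and none at Axn and Egfr (Fisher's exact test, adjusted p = 0.538). Ecdysone response genes had 6 of 13, with Eip75B (3L:17999735-17999955, rank 266), Hr78, Hr96 and Eip63E first and none at EcR and Blimp-1 (Fisher's exact test, adjusted p = 0.538). The Eip63E peak ranked only 15292 in replicate 1. Cell cycle and replication genes had 6 of 21, led by Dp (rank 436), CycE (rank 647), dup and dpa, with none at Cdk2 and Cdk4 (Fisher's exact test, adjusted p = 1). Nucleotide synthesis genes had 6 of 18, led by the uridine-cytidine kinase gene Uck (3R:24289910-24290345, rank 568), RnrS, Adsl and Ctps, with none at Adss (Fisher's exact test, adjusted p = 0.929). The Ctps peak named here (rank 1433) also lies beside the start of CG45071, a gene within Ctps.

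Lists of chromatin protein genes did not pass, and some members had high-ranking promoter peaks. Insulator and architectural protein genes had 6 of 15, with Chro (rank 15), Cp190 (3R:15275229-15275552, rank 167), Dref (rank 224) and M1BP (rank 401) the strongest, and none at CTCF and Clamp (Fisher's exact test, adjusted p = 0.596). Polycomb and trithorax genes had 5 of 16, led by ph-p (X:2137184-2137530, rank 27), brm (rank 204), E(z) (rank 618) and Trl (rank 746), with none at Pc and Pcl (Fisher's exact test, adjusted p = 0.929). Heat shock genes had 3 of 4, Hsp83 (3L:3192915-3193278, rank 25), Hsp27 (rank 161) and Hsp26 (rank 935), and Hsp22 and Hsp23 had no optimal promoter peak (Fisher's exact test, adjusted p = 0.27). No dosage compensation gene had an optimal promoter peak (0 of 4 tested; Fisher's exact test, adjusted p = 0.929), and neither Clamp nor the noncoding roX1 gene (outside the protein-coding test) had one.

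Receptor, larval cuticle (set by gene name and not by stage), eggshell and yolk, and small RNA genes gave no call in the main test. Odorant, gustatory and ionotropic receptor genes had 0 of 11 (Wilson upper bound 25.9%) and larval cuticle genes 0 of 10 (27.8%), and Gr10a, Gr10b, Ccp84Aa and Ccp84Ab had no optimal promoter peak (Fisher's exact test, adjusted p = 0.27 for both). Larval cuticle genes passed as lower with a window of 1000 bp, at 0 of 21 (log2 odds ratio -4.08). Against all annotated genes, with or without a pooled summit, receptor genes (0 of 179, log2 odds ratio -5.90), larval cuticle genes (0 of 93, -4.95), histone genes (0 of 111, -5.20) and small nucleolar RNA genes (19 of 269, -1.07) passed as lower. Of the eggshell and yolk genes, which include Cp15 and Cp16, only 1 was in the test, with no peak (Fisher's exact test, adjusted p = 1). None of the 111 replication-dependent histone genes, such as His1:CG31617 and His1:CG33801, had even a pooled summit, so that list was outside the main test. Their 0 of 111 against all annotated genes was thereby fixed, since all optimal peaks are in the pooled list. Alignments were not analysed here, so a lack of binding cannot be told from a lack of placed reads at these genes. Transfer RNA genes had 43 of 176, 24.4% (18.7 to 31.3; Fisher's exact test, adjusted p = 0.756), with tRNA:Tyr-GTA-1-8 (3R:8669220-8669521, rank 76), tRNA:Phe-GAA-1-2, tRNA:Val-CAC-2-5 and tRNA:Leu-TAA-2-1 the strongest. Against random lists of protein-coding genes from the same length bins, the transfer RNA genes passed as higher. The share expected was 16.0% (log2 odds ratio 0.75, against -0.22 in the main test). Lengths within a bin were not compared, so a match to genes as short as these is not shown. Small nuclear RNA genes had 2 of 10, snRNA:7SKa and snRNA:U2:34ABb, with none at snRNA:7SKb and snRNA:LU (Fisher's exact test, adjusted p = 0.929). Their peaks ranked only 5523 and 12603 in replicate 1. Small nucleolar RNA genes had 19 of 68, led by snoRNA:U49:66Da (Fisher's exact test, adjusted p = 1).

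**Figure D3:**
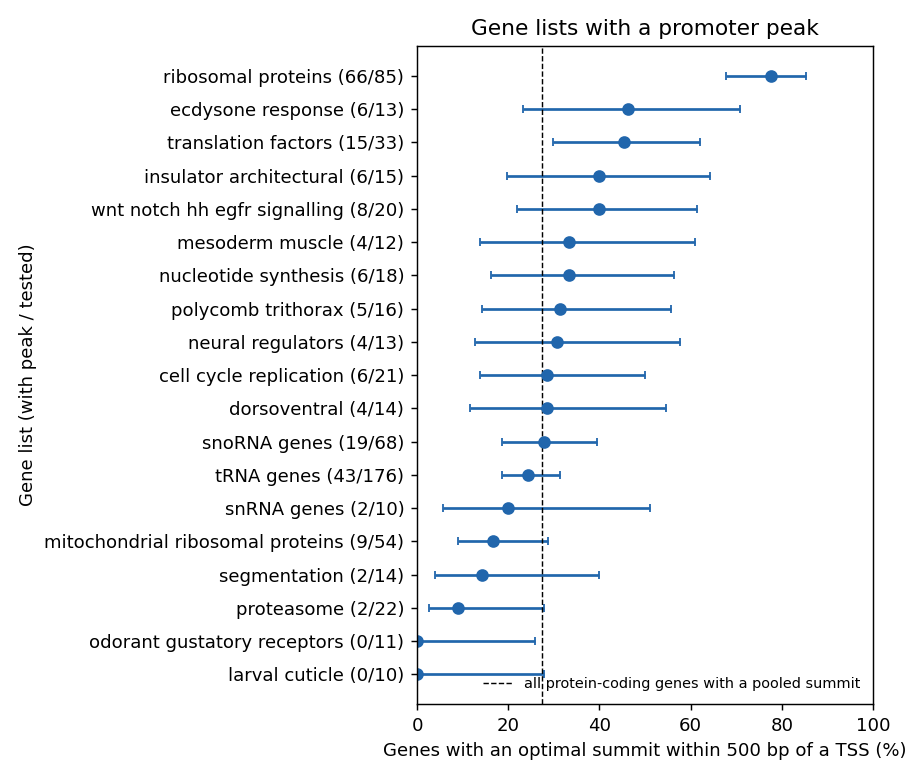
Share of genes with an optimal summit within 500 bp of a TSS (x axis, %) for each gene list with at least 10 genes tested (y axis, genes with a peak over genes tested); points are shares, bars Wilson 95% intervals, and the dashed line is the share of all protein-coding genes with a pooled summit. Ribosomal protein genes, at 77.6%, lie above every other list.

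The locus of the tagged protein itself carried a group of 6 optimal peaks. They lay within Ctps (FBgn0266452, 3L:15097914-15113003, plus strand), which contains CG45071 (FBgn0266441, 3L:15105882-15110730, plus strand). Introns held the peaks at 15098678-15099113 (rank 649), 15104304-15104536 (rank 876), 15104679-15105097 (rank 812) and 15107046-15107481 (rank 1090). Promoter windows held those at 15101530-15101965 (rank 1922) and 15105725-15105833 (rank 1433), and the latter lay beside the start of CG45071. The replicate peaks that contained the summit of the first of these ranked 415, 775 and 755 in replicates 1, 2 and 3. For the summit of the peak of rank 1922 they ranked 7660, 2901 and 792, and replicate 1 also had a peak of rank 1676 at 15101273-15101688, beside that summit. The top 3545 peaks of replicates 1, 2 and 3 included 6, 6 and 7 peaks within 2 kb of the locus. Both genes of the list had a promoter peak (2 of 2; Fisher's exact test, adjusted p = 0.27). The strongest was the same peak for both, at 15105725-15105833, so these are not 2 independent hits.

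**Figure D4:**
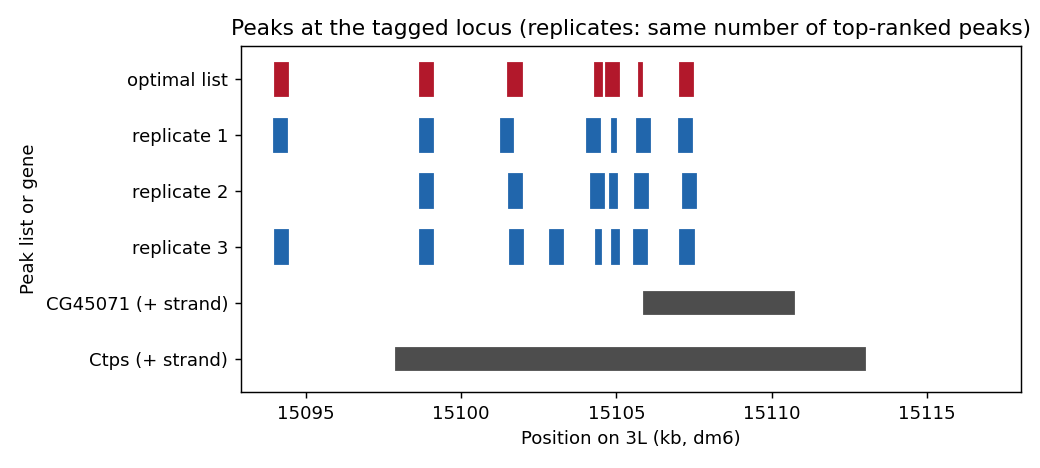
Map of 3L (x axis, kb, dm6) with the peaks of the optimal list and the 3545 top-ranked peaks of each replicate (upper rows, boxes to scale) above CG45071 and Ctps (lower rows). The optimal list has 6 peaks within Ctps, and the replicates have 6, 6 and 7 within 2 kb.

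Of 24 known sequence motifs, 9 were more frequent and 3 less frequent within 100 bp of optimal summits than of remaining summits. The homeodomain motif TAATTA was in 15.8% against 11.9% (log2 odds ratio 0.47; two-sided Fisher's exact test, adjusted p = 4.66e-09), and the GAGA factor motif in 6.74% against 4.74% (0.54; Fisher's exact test, adjusted p = 5.95e-06). The TATA box was in 4.68% against 3.14%, the DRE motif of Dref and BEAF-32 in 1.92% against 1.12%, core promoter motif 5 in 1.47% against 0.677%, the M1BP motif in 1.64% against 1.10%, CTCF in 1.18% against 0.764%, GATA in 36.7% against 33.0% and the poly(A) tract in 13.4% against 10.8%. The Pho motif (3.47% against 5.46%), the Snail E-box (5.47% against 7.64%) and CA repeats (5.28% against 7.09%) were less frequent. Zelda, Su(Hw), the Myc, Twist and Daughterless E-boxes, STAT92E, the heat shock element, Initiator, pause button and core promoter motifs 6, 7 and 8 did not pass. The pause button (9.48% against 10.7%, log2 odds ratio -0.19) passed as less frequent among optimal peaks held by the top lists of any pair of replicates (-0.34 to -0.30), in the stronger part of the list (-0.60), with a 50 bp window (-0.35) and among promoter (-0.35) and non-promoter peaks (-0.45). Against remaining windows matched on GC content and promoter class its sign turned (9.48% against 8.32%, log2 odds ratio 0.21), with no call. The Daughterless E-box passed as less frequent among non-promoter peaks (6.87% against 8.61%, log2 odds ratio -0.35).

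Windows around optimal summits were richer in A and T, with a mean GC content of 37.6% (SD 8.53, n = 3545 windows) against 42.3% (SD 8.68, n = 26455). The leading 6-mers were of the same kind, TTAAAA being in 44.4% of optimal and 28.9% of remaining windows (Fisher's exact test, adjusted p = 2.45e-71), and 19 of the first 20 held only A and T. When the remaining windows were matched on GC content and promoter class, 1 of the 24 motifs passed, GAGA factor (6.74% against 4.49%, log2 odds ratio 0.62), and none of the first 20 6-mers held only A and T. That background has 3545 windows in place of 26455, and CTCF (log2 odds ratio 0.53, against 0.65), Pho (-0.49, against -0.68) and core promoter motif 5 (0.57, against 1.14) lost the call with part of their value left. The homeodomain motif (-0.069), TATA box (0.018), Snail E-box (-0.069), DRE (-0.22), M1BP (-0.025), CA repeats (0.066), the poly(A) tract (-0.086) and GATA (-0.089) kept none of it or almost none. The GAGA factor call ended with a 50 bp window (2.88% against 2.55%, log2 odds ratio 0.18) and among promoter peaks alone (8.28% against 6.86%, log2 odds ratio 0.30), and those of M1BP (0.51 to 0.59) and CTCF (0.42 to 0.66) ended among the 2205 to 2392 optimal peaks held by the top lists of each pair of replicates. They also ended in the stronger part of the list (0.26 and 0.60). The call of M1BP ended with a 50 bp window (0.22), with overlapping peaks merged (0.52), among promoter peaks (-0.0036) and among non-promoter peaks (-0.22). The call of CTCF ended among promoter peaks (0.23). It held with a 50 bp window (1.25), among non-promoter peaks (1.03) and with overlapping peaks merged (0.65). That of DRE ended both among promoter peaks (0.24) and among non-promoter peaks (-0.095), and those of core promoter motif 5 (0.097) and CA repeats (-0.35, against -0.45) among non-promoter peaks.

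The same libraries on the older dm3 build gave 3370 optimal peaks, against 3545 on dm6. Replicates 1 and 2 shared 65.7%, replicates 1 and 3 shared 64.6% and replicates 2 and 3 shared 69.6% of their top 3370 peaks on dm3. On dm3 the X chromosome held 588 optimal peaks and chromosome 4 held 12. The dm3 lists were not annotated, since an annotation of that build was not used here.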

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

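Merging overlapping peaks and all alternatives for the side of the TSS were chosen after seeing the data. Of 611 alternatives over 70 results, 480 were rated the same, 25 weaker and 15 stronger, 85 changed sign and 6 values without a test moved. For a tested value, the same means that direction and side of the threshold were kept. Weaker then means a lost call and stronger a gained one. Where the result was a number of calls, such as gene lists past the threshold, the change in that number was rated in place of a call. The shared part of the replicates' top lists stayed between 56.6% and 74.2% for each pair, the promoter log2 odds ratio between 0.93 and 2.83 and the side of the TSS between 0.36 and 1.70, all past the threshold. Most of the sign changes were in gene lists and motifs without a call. The cause was not tested for any change below. Values are log2 odds ratios unless another unit is named. Depth is unknown, so what depth limits could not be separated from what the rank limits.

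The optimal peaks found in all replicates came to 83.2% with top lists 2 times as long, 96.6% with whole lists and 47.5% with summits within 100 bp, and to 62.2% to 67.5% in both top lists of each pair of replicates. The number of gene lists past the threshold rose from 1 to 2 with a promoter window of 1000 bp (larval cuticle genes lower), to 6 against all annotated genes (translation factors also higher, and receptor, larval cuticle, histone and small nucleolar RNA genes lower) and to 2 against random lists matched on gene length (transfer RNA genes higher). The histone call was fixed by the lack of any pooled summit at those genes. The number of motifs fell from 12 to 1 with a background matched on GC content and promoter class.

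Keeping only optimal peaks held by the top lists of both replicates of a pair, with the pooled signal and the remaining peaks still those of all 3 replicates, gave the X chromosome 0.050 to 0.082, arm 2R -0.032 to 0.034, arm 3L -0.038 to 0.054, other exons -0.047 to 0.14, dorsoventral genes -0.17 to 0.82, eggshell and yolk genes 0.46 to 0.58, small nuclear RNA genes -2.24 to 0.28, Zelda -0.026 to 0.10, core promoter motif 7 -0.15 to 0.15, Su(Hw) -0.074 to 0.046 and the Myc E-box -0.15 to 0.018. With the stronger part of the optimal list, arm 2R had -0.018, the X chromosome 0.066, dorsoventral genes -0.74, mesoderm and muscle genes -0.51, eggshell and yolk genes 0.85, Zelda 0.22, core promoter motif 7 -0.16 and Su(Hw) -0.018. Eggshell and yolk genes had 0 of 1 with a peak in all of these settings, so their positive sign comes from the 0.5 added to each cell. With overlapping peaks merged, other exons had 0.060 and STAT92E -0.025.

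With a promoter window of 100 bp, the difference in mean log10 signal was -0.0265, 5' untranslated regions had 0.031, other exons 0.21 and intergenic sequence 0.15. In the same setting Hox genes had 0.36, segmentation genes 0.72, neural regulators -0.56, mesoderm and muscle genes -1.97, Enhancer of split genes -0.38, Polycomb and trithorax genes -0.38, cell cycle and replication genes -2.82, signalling pathway genes -0.26 and small nucleolar RNA genes -0.21. Other exons had 0.29 with a window of 1000 bp and 0.070 against circular shifts, and chromosome 4 had -1.57 against arm length.

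Small nucleolar RNA genes had -1.07 against all annotated genes. With each peak counted for the nearest TSS, Polycomb and trithorax genes had -0.053, insulator and architectural genes -0.39, cell cycle and replication genes -0.25 and small nucleolar RNA genes -1.45. Against random lists matched on gene length, dorsoventral genes had -0.37, neural regulators -0.14, Polycomb and trithorax genes -0.11, transfer RNA genes 0.75 and small nuclear RNA genes 0.30. The RNA gene lists were matched there only to protein-coding genes of the same length bin.

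With a motif window of 50 bp, core promoter motif 6 had -0.12, core promoter motif 8 -0.061 and the Myc E-box -0.062. With the matched background, Zelda had 0.34, DRE -0.22, M1BP -0.025, core promoter motif 6 -0.52, core promoter motif 8 -0.15, pause button 0.21, the Twist E-box 0.14, the Daughterless E-box 0.15, homeodomain -0.069, STAT92E -0.29, CA repeats 0.066, the poly(A) tract -0.086 and GATA -0.089. Among promoter peaks alone, M1BP had -0.0036, core promoter motif 6 -0.25, Su(Hw) -0.18, the Twist E-box 0.10 and STAT92E -0.15. Among non-promoter peaks, Zelda had 0.26, DRE -0.10, M1BP -0.22, core promoter motif 7 -0.23, core promoter motif 8 -0.20 and the Myc E-box -0.14.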

Other observations

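The tests on the tagged locus, those on transfer RNA genes and housekeeping genes for the ribosomal protein pattern, and the final form of the composition test of the 8-mer were chosen after the result was seen. Since the design has 1 group, no biological explanation was tested for any of the 3 patterns by comparing groups of samples.

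The 6 optimal peaks within Ctps are a pattern that a reader of the labels would look at first. Of 964 protein-coding genes of 10 to 20 kb, 5 had at least as many optimal peaks within 2 kb, Ctps included, which is 0.519%, and the median gene had 0, so the number is not the usual one for a gene of this length. Extra copies of the tagged gene in the transgenic line may raise every fragment of the locus, and should then reach the 3' side of the midpoint of Ctps as well as the 5' side. These sides held 2 and 4 peaks (one-sided exact binomial p = 0.344), too few peaks to decide, so extra copies and binding cannot be told apart here. No optimal peak lay between 15107481 and the end of Ctps at 15113003, though weaker pooled peaks did, such as that at 15109978-15110413 (rank 26581). That gap was seen in the peaks themselves, so it decides nothing about extra copies. A first test divided there (6 peaks against 0) was dropped because its place was chosen from the peaks. Sequence coverage of the line's own input was not analysed here.

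Promoters of ribosomal protein genes may be bound by the tagged protein or may be recovered for other reasons. Short genes do not account for them, since lists matched on gene length had 21.4% with a peak against 77.6% (two-sided permutation p = 0.0002, the smallest that 10000 random lists can give). If high transcription by any polymerase were the cause, transfer RNA genes might be raised alike. The upper 95% bound of their log2 odds ratio was 0.28, below the lower bound of 2.48 for ribosomal protein genes. They did pass at 0.75 against protein-coding genes of the same length bins. Neither transcription nor the placing of reads at transfer RNA genes was measured, so these values do not decide about high transcription. Housekeeping promoters in general, raised alike, are argued against by mitochondrial ribosomal protein, proteasome, nucleotide synthesis and translation factor genes, whose upper 95% bounds of 0.14, 0.25, 1.83 and 2.13 were all below 2.48. A smaller rise shared with translation factor genes (log2 odds ratio 1.15, lower 95% bound 0.17) stays open. So do open chromatin and high transcription, by any polymerase or by RNA polymerase II in particular. Transcription and chromatin access were not measured in these files.

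A sequence element was searched for among all 8-mers, choosing on alternate windows matched on GC content and promoter class and testing on the others. The leading 8-mer was CACAGTGG, in 3.89% of optimal and 1.64% of matched remaining windows of the part that had not chosen it (log2 odds ratio 1.27; two-sided Fisher's exact test, p = 5.2e-05). That argues against GC content, promoter class or the choice among many 8-mers as its whole cause. Composition beyond GC content and annotation classes other than promoter were not matched, so they stay open. Copies of a repeat are argued against as well, since 1.33% of its matches lay in soft-masked sequence, against 20.6% of all bases of the optimal windows. A directly bound site might lie nearer to the summit in optimal windows, and an element of the wider region at a like distance, but matches were farther from it, at a mean distance of 56.5 bp (SD 27.1, n = 140) in optimal and 49.1 bp (SD 27.4, n = 398) in remaining windows (two-sided permutation p = 0.0053). That result was not foreseen by either condition set beforehand, so a bound site and an element of the wider region cannot be told apart here.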
